A study of Arabidopsis thaliana with 12 samples.

How the data were processed

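Transcript levels were measured on an array in 12 samples of total RNA from Arabidopsis thaliana grown on soil, 6 from wild type (WT, ecotype Columbia) and 6 from the pete2 mutant. The sample titles name soil for pete2 only. The labels number the samples 1 to 6 in each group and do not say whether the samples came from separate plants, so p-values measure only the spread between these samples, which may be technical.

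The deposited table holds 1 linear intensity per probe and sample, for 3439 probes. The scanner, background correction, averaging of spots and scaling of the deposited intensity values are not given in the sources used here. The values run from exactly 0 to a ceiling just under 100 that 2 to 7 probes share in every sample, so low and high intensities were limited before deposit, and a probe listed at 0 has no measured level. Sample medians and totals differed, so the values were not taken as scaled between samples. The number of arrays and the share of probes at 0 limit the precision, and no background level is given from which a detection limit could be set.

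Probes were named from the platform's table of probes and genes. Of the 3439 probes, 692 had a single gene, 870 had several and 1877 were not listed there. No value was given to a gene from a probe with several genes. Such probes were normalized and tested like the others and are part of the call counts over all probes. The later comparison of partner probes that list a gene in common uses them as well. Among the gene lists, they enter only the joined photosynthesis lists of the closing section, where they are named as shared. Of the 692 probes, 690 matched a gene of the RefSeq annotation of assembly TAIR10.1, which was used for symbols only. No coordinates are given because the array's genome build is not given in the sources used here.

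Intensities were quantile normalized between samples. Values at or below a floor, the 1st percentile of the positive normalized values (0.00560), were set to that floor, and log2 was taken. Values deposited as 0 were set to the floor as well. A first calculation had let the normalization move tied zeros to levels of their own in each sample. That step was corrected, and 118 probes at 0 in all 12 samples were left out, after its calls had been seen. This left 3321 probes for testing, of which 665 had a single gene.

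The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) and Benjamini-Hochberg adjustment over all probes tested, with a threshold of 0.05 on the adjusted p. Differences are log2 pete2 minus WT with the standard error (SE) of the fit, and group levels are normalized intensities with their standard deviation (SD).

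The plan, fixed before the data were examined, was to average samples of a group that form close pairs, where the SD of log2 differences within pairs was below 0.5 of that between other samples. For samples 1 and 2, 3 and 4, and 5 and 6 the ratio was 0.621 in WT and 0.787 in pete2, so the 12 samples entered separately. Over the 263 brightest probes, a set chosen after seeing the data, the ratios were 0.368 and 0.373. For this reason the fit with the 3 pairs of each group averaged, which was planned as an alternative, is given beside the main counts. A fit with the pairs as a random block (duplicateCorrelation), added after seeing the data, is given as well. The ratios rest on medians over pairs, and the plan also required the samples of a pair to be nearest to each other. Over all probes pete2 samples 5 and 6 were not, with an SD of 2.32 against 2.08 to 2.17 to samples 3 and 4. Over the brightest probes sample 5 was nearest to sample 6 (0.732), but sample 6 lay nearer to samples 3 and 4 (0.656 and 0.689).

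The calculation was tested on simulated data with 3321 probes, of which 200 were changed, in 20 runs. With no correlation within pairs, 6.49% of the calls over 12 samples were false. With the correlation estimated here, 0.525, 34.3% were false over 12 samples, 5.22% with the random block and 0.357% with pairs averaged. The recovered share of 2-fold changes was then 22.3%, 6.45% and 0.10% in the same order, and that of 4-fold changes was 52.5%, 29.9% and 4.25%. The simulated errors were normal, with the same correlation for every probe, the same spread in both groups and no zeros. The measured data depart from this, so these shares need not hold for them.

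The named genes are, by a rule fixed before the data were examined, PETE2 and PETE1, the 8 single-gene probes with the largest rise and the 8 with the largest fall among called probes, and up to 2 called members of each gene list. A ranked gene also had to be above 0 in at least 1 sample of each group, a condition added after seeing the data. AT3G09250, added because it was also called with pairs averaged, and 4 unnamed probes were singled out after their values were seen. The 29 gene lists, with 317 loci, were also fixed beforehand and cover photosynthesis, plastid functions, metabolism, stress and other cell types. Lists with at least 3 measured members were tested with camera (preset correlation 0.01) and, beside it, with an estimated correlation and with fry. Of the lists matched by name pattern, 0 genes were kept and 1 was dropped because the pattern matched part of another word.

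Two-sided exact permutation tests compared whole-sample measures between groups. The alternatives covered the sample number as a block, pairs, scaling, dim probes, the variance model, sample weights, the floor, each sample left out, zeros, samples with many zeros and probe positions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.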

Results

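The pete2 mutant of Arabidopsis lacks an isoform of plastocyanin, the copper protein that carries electrons to photosystem I in the thylakoid lumen. The series asks which transcripts differed between soil-grown pete2 and wild-type (WT) plants. It holds 6 WT and 6 pete2 samples on an array of 3439 probes.

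The samples differed in how many probes were listed at 0, mostly among those of pete2. The share of probes at 0 was 16.7% ± 0.821 (SD, n = 6) in WT and 22.8% ± 5.73 (SD, n = 6) in pete2, with a two-sided exact permutation p of 0.0173 and a Benjamini-Hochberg value of 0.0866 over 5 measures, which missed the threshold. The shares were 30.7% and 28.6% in pete2 samples 5 and 6, and 17.2% and 17.1% in pete2 samples 1 and 2. With samples 1 and 2, 3 and 4, and 5 and 6 of each group averaged, the exact permutation p was 0.20, and 0.10 is the smallest that 3 against 3 allow. The median deposited intensity was 0.161 ± 0.0249 (SD, n = 6) in WT and 0.110 ± 0.0584 (SD, n = 6) in pete2, and the difference did not pass the test (exact permutation p = 0.0758). The 99th percentile went the other way, at 12.8 ± 1.71 in WT and 16.7 ± 3.74 in pete2 (SD, n = 6 each, exact permutation p = 0.0476, Benjamini-Hochberg 0.119). The total intensity was 3009 in WT and 2990 in pete2 (exact permutation p = 0.835), and means of 4.33 and 4.5 probes lay at the ceiling.

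**Figure D1:**
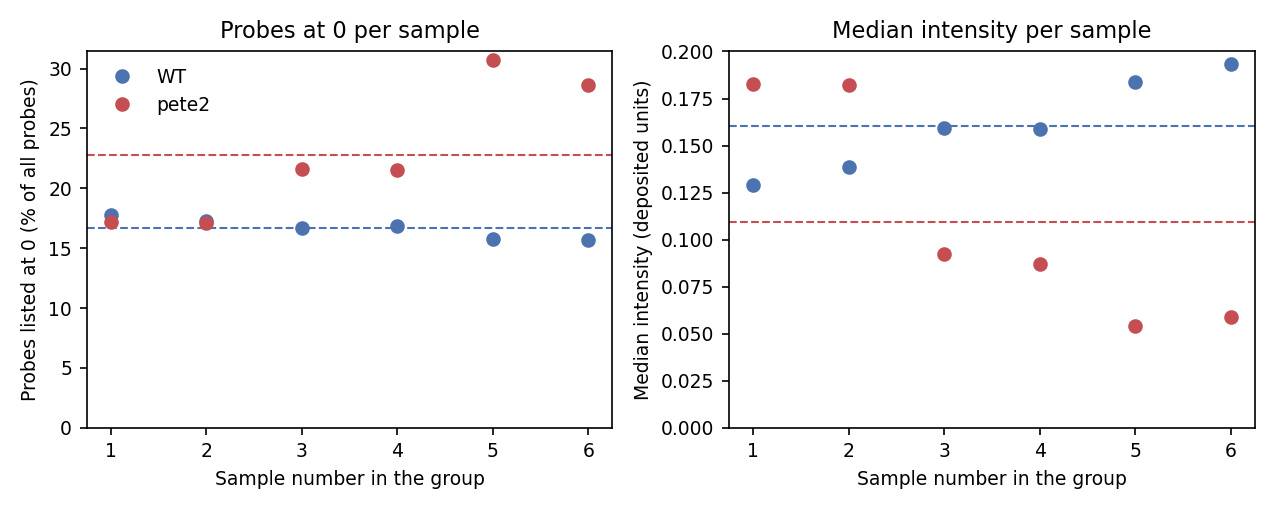
Percent of probes listed at 0 (left) and median deposited intensity (right) in each sample, against the sample number, with dashed lines at the group means. Samples 1 and 2 of pete2 lie close to WT in the share at 0, while pete2 samples 5 and 6 lie at 30.7% and 28.6%.

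The targeted gene could not be checked. PETE2 and its paralog PETE1 are not named in the probe table, so no level of either is given and the genotype labels were not tested against the data.

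PSAN (AT5G64040), a lumenal subunit of photosystem I, rose from a normalized intensity of 3.78 ± 0.459 (SD, n = 6) in WT to 9.68 ± 2.21 (SD, n = 6) in pete2, a log2 difference of 1.33 ± 0.172 (SE, adjusted p = 0.00034). PSBY (AT1G67740), a small protein of photosystem II, rose by 0.91 ± 0.203 (SE) on the log2 scale, from 2.36 ± 0.369 to 4.57 ± 1.45 (SD, n = 6 each, adjusted p = 0.0126). With samples 1 and 2, 3 and 4, and 5 and 6 averaged as pairs, neither passed (adjusted p = 0.132 for PSAN and 0.286 for PSBY). AT4G13550 rose 4.12-fold, from 0.276 ± 0.0326 to 1.13 ± 0.0494 (SD, n = 6 each, adjusted p = 2.21e-06). AT3G09250 had 2.13 ± 0.436 in WT and 0.396 ± 0.0938 in pete2 (SD, n = 6 each), which was 5.42-fold lower in pete2 (adjusted p = 8.38e-06).

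Of the 3321 probes tested, 372 were called over the 12 separate samples, 163 higher and 209 lower in pete2. Of these calls 82 had at least 1 value at 0, and in 10 a whole group was at 0. The 290 calls above 0 in all samples were 153 higher and 137 lower, so the excess of falls lay among probes with zeros. This subset leaves out falls to 0, so it does not test the balance. In simulated data with the correlation within pairs estimated here, 34.3% of calls over 12 samples were false. That setting had 200 changed probes and gave a mean of 115 calls, so 34.3% is no estimate for the 372. In the measured data 168 were called with the pairs as a random block, 63 higher and 105 lower. With the pairs averaged 11 were called, 3 higher and 8 lower. All 168 and all 11 were among the 372. Among the 665 probes with a single gene, 81 were called over 12 samples (32 higher, 49 lower), 38 with the random block (13 higher, 25 lower) and 2 with pairs averaged, which were AT4G13550 and AT3G09250 (adjusted p = 0.039 for both).

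**Figure D2:**
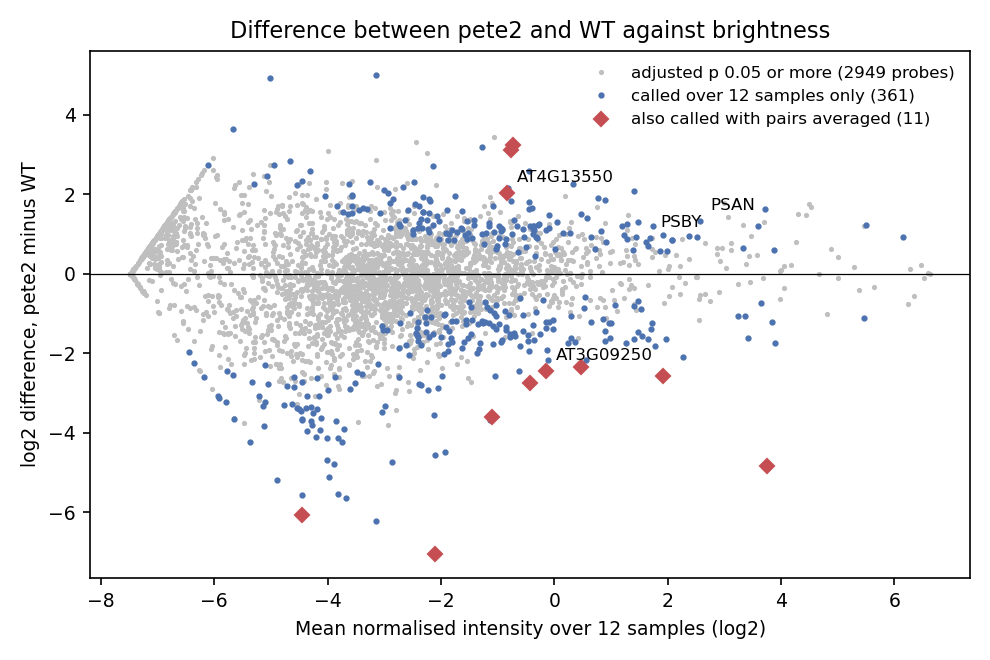
Log2 difference between pete2 and WT against mean normalized intensity (log2) for the 3321 tested probes. Blue points are probes called only with 12 separate samples, red diamonds are the 11 probes also called with pairs averaged, and grey points passed neither. Points along the slanted edges at the left are probes at the floor in 1 group.

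AT4G13550 was among the 8 genes with the largest rises. Of the other 7, AT5G63490 led with a log2 difference of 2.31 ± 0.438 (SE, adjusted p = 0.00509), followed by AT3G27550 with 2.19 ± 0.398 (SE, adjusted p = 0.00371). AT4G19900 rose from a normalized intensity of 1.42 ± 0.747 to 5.54 ± 1.17 (SD, n = 6 each, adjusted p = 0.00057). AT4G32060 encodes MICU, a protein of mitochondrial calcium uptake, and rose from 1.03 ± 0.354 to 3.67 ± 1.11 (SD, n = 6 each, adjusted p = 0.000646). AT3G52070, AT1G06510 and AT4G27250 rose by 1.95, 1.92 and 1.88 on the log2 scale, with adjusted p of 0.0161, 0.0266 and 0.0183. With the random block these 3 genes missed the threshold, at 0.104, 0.0714 and 0.0845. With pairs averaged, the adjusted p of these 7 genes lay between 0.113 (AT4G19900) and 0.295 (AT1G06510), so AT4G13550 was the only one of the 8 to pass. AT1G06510 also missed the threshold without WT sample 3 (adjusted p = 0.0573), and on the intensities as deposited AT5G63490, AT3G27550, AT3G52070, AT1G06510 and AT4G27250 did so, with adjusted p between 0.0688 and 0.261. AT3G52070 also missed it without samples 5 and 6 of both groups (adjusted p = 0.0795). As deposited, AT1G06510 was higher in pete2 in samples 1 to 4 but lower in samples 5 and 6 (0.204 and 0.176, against 0.317 and 0.261 in WT). Only normalization gave it a rise there, of 0.757 on the log2 scale. Deposited AT3G52070 was 0.0406 and 0.0823 in pete2 samples 3 and 4, against 0.0979 and 0.0457 in WT.

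Among the 8 genes with the largest falls, AT1G02020 was above 0 in every sample and fell by 4.48 ± 0.941 (SE) on the log2 scale, from 1.82 ± 1.80 in WT to 0.108 ± 0.106 in pete2 (SD, n = 6 each, adjusted p = 0.0091). AT5G17630, which encodes a xylulose 5-phosphate translocator of the plastid envelope, fell by 3.83 ± 0.582 (SE, adjusted p = 0.00101), and AT2G46910, of the fibrillin family of plastid lipid-associated proteins, fell by 4.14 ± 0.918 (SE, adjusted p = 0.012). AT2G46300 fell by 5.12 on the log2 scale (adjusted p = 0.00663) and AT5G24690 had a log2 difference of -3.82 (adjusted p = 0.0116). AT5G48130 fell by 3.37 (adjusted p = 0.017), AT3G52550 by 3.71 (adjusted p = 0.0416) and AT4G23110 by 3.35 (adjusted p = 0.0407). All of these except AT1G02020 were listed at 0 in 4 of the 6 pete2 samples and in 0 WT samples, and AT1G02020 lay at the floor in pete2 sample 1, so the size and rank of these falls depend on the floor. The zeros lay in pete2 samples 3 to 6, which held more zeros over the whole array, except for AT5G24690 and AT5G48130. AT5G24690 was at 0 in pete2 samples 1 to 4, and AT5G48130 in samples 2, 3, 5 and 6. With the floor at the 10th percentile the log2 difference was -2.82 for AT2G46300, -3.73 for AT1G02020, -2.16 for AT2G46910 and -1.30 for AT5G17630. It was -1.84 for AT5G24690, -1.40 for AT5G48130, -1.74 for AT3G52550 and -1.38 for AT4G23110, and the last 2 lost their calls (adjusted p = 0.0514 and 0.0648). AT3G09250, above 0 in every sample, had -2.44 with this floor, a larger fall than all of these but AT2G46300 and AT1G02020. With cyclic loess AT5G48130 and AT4G23110 missed the threshold (adjusted p = 0.0709 and 0.0628). With the random block AT3G52550, AT5G48130 and AT4G23110 missed the threshold, at adjusted p of 0.0803, 0.166 and 0.0882, and with pairs averaged none of the 8 passed, the lowest being 0.112 for AT5G17630. AT3G52550 had no fall in samples 1 and 2, where its log2 difference was 0.024, and it lost its call in 10 of the 12 fits that left out 1 sample, as AT4G23110 did in 9, with adjusted p up to 0.0882 and 0.0844. Without pete2 samples 5 and 6, which held the most zeros, AT2G46910, AT5G48130, AT4G23110 and AT3G52550 missed the threshold, at adjusted p of 0.0534, 0.0685, 0.138 and 0.148, and so did AT1G06510 and AT4G27250 among the rises, at 0.0636 and 0.0729. The fall of AT5G24690 was larger without these samples, at -5.20 (adjusted p = 5.32e-05).

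**Figure D3:**
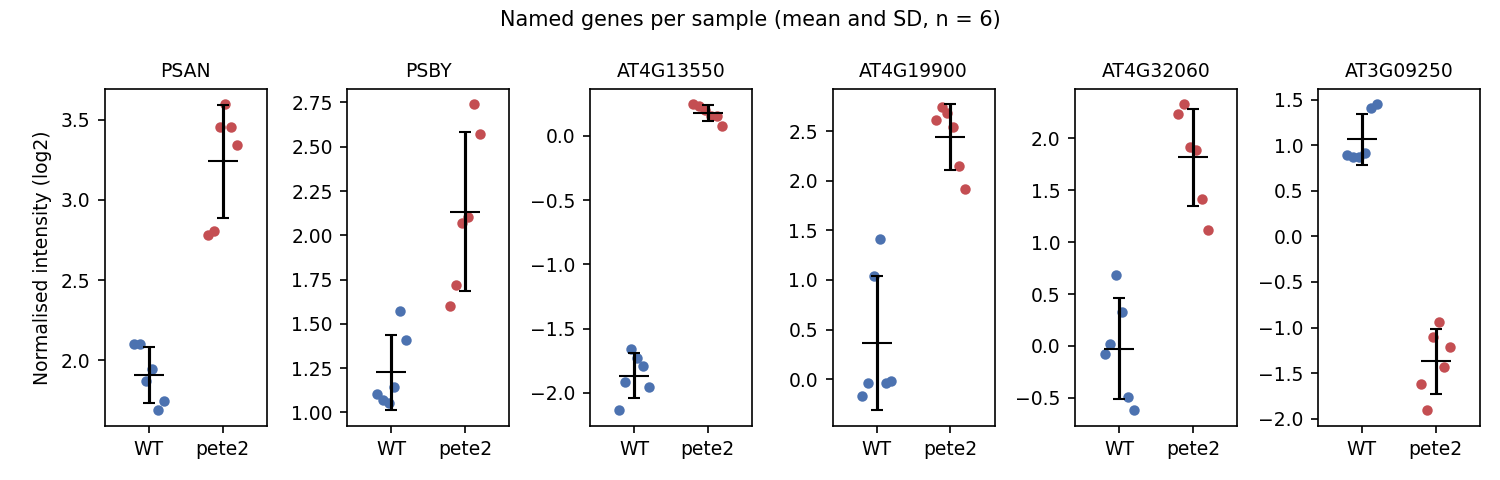
Normalized intensity (log2) of 6 named genes in each WT (blue) and pete2 (red) sample, with the mean and SD of each group (n = 6), and a vertical axis of its own for each gene. Points are ordered by sample number, and the groups do not overlap for any of these genes.

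Unnamed probes also showed large differences. Probe 3524 was 28.8-fold lower in pete2 by the difference of mean log2 values (adjusted p = 9.72e-06, and 0.0377 with pairs averaged). Its normalized intensity was 72.3 ± 6.55 in WT and 3.13 ± 2.35 in pete2 (SD, n = 6 each). The deposited values ran from 48.4 to 92.5 in WT and from 1.07 to 5.79 in pete2. Normalization gave WT samples 2, 3 and 6 the same value (74.2), so the WT SD understates the spread as deposited. Probe 1144 fell by 3.69 ± 0.36 (SE) on the log2 scale (adjusted p = 3.44e-05, and 0.057 with pairs averaged). Probes 3491 and 3452 rose 9.16-fold and 8.69-fold (adjusted p = 0.00663 and 0.000379), and with pairs averaged their adjusted p was 0.193 and 0.107. Without samples 5 and 6 of both groups the log2 difference of probe 3491 was 2.15. The log2 difference of probe 3524 over all 12 samples was -4.85 with quantile normalization and -4.17 with median centring. These 4 probes were above 0 in all samples and were chosen after their values were seen.

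Of the 29 gene lists fixed beforehand, 9 had measured members, 14 genes in all. Of these genes 2 rose, 0 fell and 8 had a positive log2 difference, SBPASE among them although most of its values were 0. In photosystem II, 1 of 3 measured members rose (PSBY), while PSBW had a log2 difference of 0.61 and PSB27, a factor of photosystem II assembly and repair, one of -0.62, and neither passed the test. Its shift relative to other genes did not pass the test (camera p = 0.173, and p = 0.294 with an estimated correlation). The directional test of fry, which sets the list against no change, gave 0.0773. Photosystem I was represented by PSAN alone. Under median centring of the samples the log2 differences were larger, 2.12 for PSAN and 1.47 for PSBY, and PSBY missed the threshold (adjusted p = 0.0832). With the random block PSAN and PSBY both passed, at 0.000667 and 0.0272.

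The antenna protein gene LHB1B2 had a normalized intensity of 24.3 ± 18.2 in WT and 37.7 ± 20.9 in pete2 (SD, n = 6 each, adjusted p = 0.342). Of the Calvin cycle genes, PRK, which encodes phosphoribulokinase, had a log2 difference of 0.28 ± 0.283 (SE, adjusted p = 0.542), and SBPASE was listed at 0 in 6 WT and 4 pete2 samples. CCS, the copper chaperone of superoxide dismutase, had a log2 difference of 0.85 ± 0.29 (SE, adjusted p = 0.0797). Adjusted over the list alone, PSBY passed, 1 of 3 members. CCS and PSAN are the single measured members of their lists, so that adjustment leaves their unadjusted p, which lay under 0.05, and is no test beyond it. In tetrapyrrole biosynthesis, AT1G74470 had a log2 difference of 0.76 and CHLM, the magnesium protoporphyrin methyltransferase, one of -1.02 (adjusted p = 0.221 and 0.143). NTRC and AT3G52960 of the antioxidant list had log2 differences of -0.34 and -1.17, FATB of lipid synthesis had -0.50 and APS4 of sulphur assimilation had -0.10, and none of these passed the test. For NTRC and FATB the log2 difference was negative while the mean intensity was higher in pete2. The other 20 lists had no measured member, among them the plastocyanin genes and the markers of roots, flowers, vascular and guard cells, dividing cells and senescence, so a difference in tissue make-up was not examined.

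After quantile normalization, which makes the samples' distributions alike and so largely sets this share, 49.3% of the tested probes were higher in pete2, against 31.2% without scaling. The share was 47.3%, 47.9% and 45.2% in the 3 pairs taken singly. Of the 372 called probes 43.8% were higher, against 13.5% of 445 calls on the intensities as deposited. Without scaling the median log2 difference over all tested probes was -0.63, so the calls above are relative to that shift.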

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

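The tests below of pairs of samples, of the shift without scaling and of probe positions were chosen after the patterns were seen, and the splits of the samples were planned before.

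In pete2, AT2G46300 (probe 2667) and AT5G17630 (probe 1298) each had a sample far above the rest. The gap of pete2 sample 2 to the nearest other sample was 0.789 of the group's range for AT2G46300 and 1 for AT5G17630, against a critical value of 0.625 for 6 samples. Chance gives about 1 such case in 20 groups, and 2 of 56 groups tested were found. For both genes 4 of the other pete2 samples were listed at 0. For AT5G17630 all 5 others lay at the floor, so any value above the floor gives a gap of 1, and the comparison with the critical value tests nothing there.

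For the 372 calls over 12 samples, 1 of 100 splits of the samples into 6 and 6, the real one, gave as many, and the highest of the others gave 5. This would exclude chance only if the 12 samples were independent, and the correlation within pairs was estimated at 0.525. Splits that kept the pairs together gave up to 63 calls with the 12 samples separate, in the split that set WT samples 1 to 4 and pete2 samples 1 and 2 against the rest. For the 11 calls with pairs averaged, 1 of 10 splits, the real one, gave as many and the highest other gave 0. With 10 splits no share under 0.05 can be reached, so chance is not excluded.

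Many more probes were called over 12 samples than with pairs averaged (372 against 11). A candidate explanation is that samples 1 and 2, 3 and 4, and 5 and 6 are repeat measurements of the same material. Of 225 ways of pairing the samples within both groups, 1, that of the consecutive numbers, had a mean within-pair SD as small as 1.44, and the next was 1.49. That mean does not show each pair to be close. Over all probes pete2 samples 5 and 6 differed more from each other (SD 2.32) than from samples 3 and 4 (2.08 to 2.17). No biological explanation for the pairs was tested, and the labels do not say what the numbers mean. If the pairs are repeats, the number of independent samples is 3 per group.

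Without scaling, most calls were lower in pete2 (385 of 445). A genotype that lowers most transcripts would shift all 3 pairs down, but the median differences were 0.169, -0.627 and -1.40, so the highest was above 0. With 3 pairs and arrays of unknown scale this does not decide. A larger background subtraction in some pete2 samples could lower dim probes more than bright ones, and the middle part of the brightness range lay -0.680 log2 units from the brightest probes. In samples 1 and 2, however, both middle parts were higher (0.294 and 0.298, against -0.00189 for the brightest), and the dimmest part, where 55.2% of values were 0, had 0.0359 against -0.322, so the genotype effect and the technical one cannot be told apart from these values.

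Probes whose number is a multiple of 6 were listed at 0 in 74.3% of their values, against 15.3% for the other probes, and more often in WT (81.2%) than in pete2 (67.3%), while each of the 5 other classes of number had more zeros in pete2. The period was found by scanning many lags and divisors. Of the 261 multiples of 6, 35 had partner probes at other numbers that list a gene in common. The partners were at 0 in a median of 8.33% of samples, against 83.3% for these 35 (29 more often at 0, 1 less often, 5 tied, two-sided exact sign p = 5.77e-08). This argues against low expression of the genes for these 35 only. A partner may share only some of a probe's genes, and the other multiples of 6 were not tested. Whether these array positions hold little usable probe stays open, since the share at 0 is the pattern itself. Without these probes 379 were called, 366 of them among the 372.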

How the results depend on the processing

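Of the alternatives, those on pairs as a random block, probes above 0 in all samples, samples 5 and 6, probe positions and the unscaled list with an estimated correlation were added after seeing the data. The direction of no named gene or probe reversed under these alternatives, which was not counted for the other probes. Over probes above 0 in all samples 213 were higher and 174 lower, but this filter drops falls to 0 and is no test. Of 613 named-item values under alternatives, 544 kept direction and call and 69 lost the call, 20 of these with pairs averaged. AT4G13550, AT3G09250 and probe 3524 kept theirs in all 27. AT3G09250 was named because it was called with pairs averaged, so that alternative was no test for it. With pairs averaged 11 probes were called (3 higher, 8 lower), and with pairs as a random block 168 (63 higher, 105 lower). In simulated data averaging lowered the mean number of calls from 62.4 to 25.6 with no correlation within pairs and from 115 to 4.4 with that estimated here. As deposited, with no scaling, 60 were higher and 385 lower, 31.2% of tested probes were higher, and the photosystem II list passed the threshold in limma's camera with the preset correlation, adjusted p = 0.0224 (equal to the unadjusted value with 1 list tested; 0.0224 to 0.398 over its alternatives). With an estimated correlation it did not pass on these values, adjusted p = 0.10, and both are relative to other genes, whose values lay lower in pete2 without scaling (median log2 difference over all probes -0.63). The share of tested probes higher in pete2 was 52.2% with cyclic loess, 44.9% without the dimmest 25% of probes, 51.2% with sample weights, 56.7% with a floor at the 10th percentile, 54.1% over probes above 0 in all 12 samples and 51.2% without samples 5 and 6 of both groups, so its side of 50 depends on these choices. For the random block, the list without scaling and these shares the cause was not tested. Leaving out 1 sample at a time gave 287 to 423 calls, 119 to 196 higher and 163 to 227 lower, 48.5% to 50.1% of probes higher, and list p of 0.113 to 0.398. Samples with the same number correlated across groups by 0.0198 and 0.0409 for numbers 1 and 2, and by 0.136 to 0.283 for numbers 3 to 6. Because not every number correlated, the main fit took the samples to share only a number. Yet 8 of 12 samples, those numbered 3 to 6, correlated best with their own number, so a pairing by number is not excluded. With the sample number as a replicate block 324 probes were called (142 higher, 182 lower), 275 of them among the 372, the share was 49.3%, the list p was 0.231, and AT3G52070 and AT3G52550 missed the threshold (adjusted p = 0.0616 and 0.0675). The list test takes no random block. Alternatives for PETE2 and PETE1 were not run, as neither is named, nor was the mean of all probes of a gene, as no list member tested has several. The background and depth of the arrays are unknown, and 118 probes at 0 in all samples could not be tested.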

Other observations

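The test of joined lists below was chosen after the values of the separate lists were seen.

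The photosystem, antenna, electron transport, ATP synthase and Calvin cycle lists were joined, with probes whose several genes all belong to these lists included. Of the 9 probes 8 had a positive log2 difference, but only 2 passed the test (PSAN and PSBY, both higher), and the median was 0.91. A probe shared by the ATP synthase genes ATPC1 and ATPC2 had a log2 difference of 1.32 ± 0.519 (SE, adjusted p = 0.127), a probe shared by the antenna genes of the LHCB4 family had 0.36 ± 0.46 (SE, adjusted p = 0.636) and a positive difference in only 1 of 3 pairs, and PSB27 was the exception at -0.62. Without SBPASE, listed at 0 in 10 of the 12 samples, the median was 0.76. The median was 0.84 as deposited, where 6 of 9 were positive and the median of all probes was -0.63, 1.47 with median centring and 0.84 with cyclic loess, with 8 of 9 positive in both.

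The hypothesis that transcripts of the photosynthetic apparatus are higher in pete2 than other transcripts of like brightness was tested against 10000 random lists matched on mean intensity. A share of 0.0312 of these had a median as high, and their own median was 0.30. Camera set the list against a background of 664 probes that was not matched on intensity, so it does not test the comparison at like brightness. It gave p = 0.00292 with the preset correlation and p = 0.0437 with an estimated correlation over 12 samples, but p = 0.0107 and p = 0.107 with pairs averaged. The random lists took no account of correlation between genes, and camera did not match intensity, so the hypothesis stays open. The camera result also depends on the correlation taken between genes and on whether the pairs count as independent samples. The lists were also joined after their values were seen, so these p-values are no independent test.

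Deviations of neighbouring probe numbers from the group means correlated by 0.183 to 0.394 in WT samples and by 0.0988 to 0.215 in pete2 samples. For the difference between genotypes the value was 0.0244, within the 0.0649 reached by 200 shuffles of probe order.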
